A study of Homo sapiens with 8 samples.

How the data were processed

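The samples were 4 control and 4 shHNRNPC samples of KYSE150 cells, grouped by the genotype given in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and poly(A) RNA libraries were made with the VAHTS Universal kit. Per the series design text, they were sequenced as paired-end reads on a NovaSeq instrument and low-quality reads were removed with fastp, and the genome build was hg38 per the submitters' processing notes. The aligner, counting tool, annotation release and strand setting are not given in the sources used here. Without a stated strand setting, reads from overlapping genes on opposite strands cannot be separated, so the share of exon bases overlapping another gene is given where it exceeds 20%. The deposited values are raw read counts per gene and sample, not normalised, for 16082 genes, and every gene had at least 1 count over the samples. Of these genes 15996 were protein coding, and 0 came from the mitochondrial genome.

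Library totals were 28323403 to 34913500 counts, and the libraries detected 13855 to 14223 genes. Replicate libraries were compared by a chi-square test of counts over genes with at least 10 counts in the pair: the statistic per degree of freedom was 2.66 to 3.70 within groups and 109 to 124 between groups, so no library repeated another within sampling noise.

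Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total count 15) and libraries were scaled with TMM factors. Counts were tested with edgeR's quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) on the group term alone, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Single values were compared with exact two-sided permutation tests over all 70 assignments.

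Gene lists were tested with limma's camera on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation. The fry tests ask whether the genes of a list move on balance in a given direction (directional) or change in either direction (mixed), and neither compares the list with other genes. Adjusted p-values of the lists are over the 31 lists tested. A zinc finger class, all genes named ZNF followed by digits, was tested on its own.

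Genes were named by a rule fixed before the data were examined. It took HNRNPC and BOLA3; the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups; and the 5 most abundant genes past the threshold with an absolute log2 fold change of at least 1. From each list it took up to 4 members past the threshold with the largest absolute log2 fold change and at least 1 CPM, or the 2 with the smallest p where fewer than 2 passed. It also took the 3 most abundant genes of each list of other cell types and the 3 noncoding genes with the largest absolute log2 fold change within the same limits of 5 CPM and no overlap. Genes outside this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

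Gene positions and biotypes came from the RefSeq annotation of GRCh38, matched by gene identifier for 16038 genes, and transcript lengths, GC content, exons and 3' UTRs from GENCODE release 29, which matched 15951 genes. The submitters' annotation release may differ from both. For 11756 tested genes with an annotated 3' UTR of at least 50 bases, every 7-base word carried by at least 100 of them (15839 words) was scored by the difference in log2 fold change between carriers and other genes, after adjustment for 3' UTR length and GC content and expression by quadratic regression.

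Tests were checked on simulated counts for 12001 genes drawn from the means and library sizes of these samples. For 4 simulated control against 4 simulated shHNRNPC libraries, edgeR recovered 40 of 50 genes changed 1.25-fold, 43 of 50 changed 1.5-fold and all 50 changed 2-fold or 4-fold, and called 14 of 11624 unchanged genes. On the same data camera called 2 of 2 shifted and 0 of 20 unshifted lists. The simulated genes varied independently, so this does not check the preset correlation for lists whose genes vary together. Few simulated genes were changed, against 11624 unchanged, whereas 77.3% of tested genes were called in the data. The simulation therefore does not check the scaling, or the calls of small changes, where most genes change. The word scores were checked apart from the simulation, on the measured log2 fold changes shuffled across genes. A shift of -0.2 planted there in carriers of a word ranked that word first in 5 of 5 trials, with no rarer words planted. Alternatives were DESeq2, limma-voom, other scalings, no filter and a filter of 1 CPM in 4 samples, the replicate number as a block, removal of a loess trend on length and GC content, an adjusted p of 0.01, and leaving out each library in turn. Exon use was not analysed, since it needs reads.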

Results

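Poly(A) RNA was sequenced from KYSE150 cells, an established human esophageal squamous cell carcinoma line, in 4 control samples and 4 samples in which HNRNPC was knocked down with a short hairpin RNA (shHNRNPC). HNRNPC is a nuclear RNA-binding protein that coats nascent transcripts and shapes splicing. The series concerns its effect on exon 3 of BOLA3, a mitochondrial iron-sulfur cluster assembly factor. The deposited table held read counts for 16082 genes, and library totals ranged from 28323403 to 34913500 counts. Mean totals did not differ detectably between the groups (exact permutation test, two-sided, p = 0.657, n = 4 per group). Nothing in the labels states that the samples came from separate cultures, so the p-values given here measure only the spread between these samples, which may be technical.

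HNRNPC itself was strongly depleted in every knockdown library. Its CPM (counts scaled by library size and TMM factor) were 587 ± 12.5 (SD, n = 4) in the control samples and 33.9 ± 1.81 in the shHNRNPC samples, leaving 5.78% of the control level. The raw counts spanned 18277 to 20334 in the control libraries and 952 to 1142 in the knockdown libraries. The log2 fold change was -4.12 (SE 0.027), the strongest evidence of any gene by edgeR's quasi-likelihood test (adjusted p = 5.7e-75). An exact two-sided permutation test gave p = 0.0286, the smallest value that the 70 assignments of 4 and 4 samples allow. The HNRNPC gene lies on chromosome 14 from 21209147 to 21269442 in the RefSeq annotation of GRCh38.

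BOLA3 also fell. Its level was 17.2 ± 0.652 CPM (SD, n = 4) in the control samples and 7.82 ± 1.13 CPM in the shHNRNPC samples, or 45.5% of control, with raw counts of 527 to 592 and 219 to 323. The log2 fold change was -1.13 (SE 0.083, edgeR adjusted p = 1.6e-19), and the exact two-sided permutation test gave p = 0.0286. BOLA3 lies on chromosome 2 from 74135400 to 74147912. In GENCODE release 29 its 4-exon coding transcript contains exon 3, a coding exon of 89 bp at 74142272 to 74142360, and the 3-exon coding transcript lacks it. Counts per gene do not distinguish these transcripts, so inclusion of exon 3 was not measured here.

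**Figure D1:**
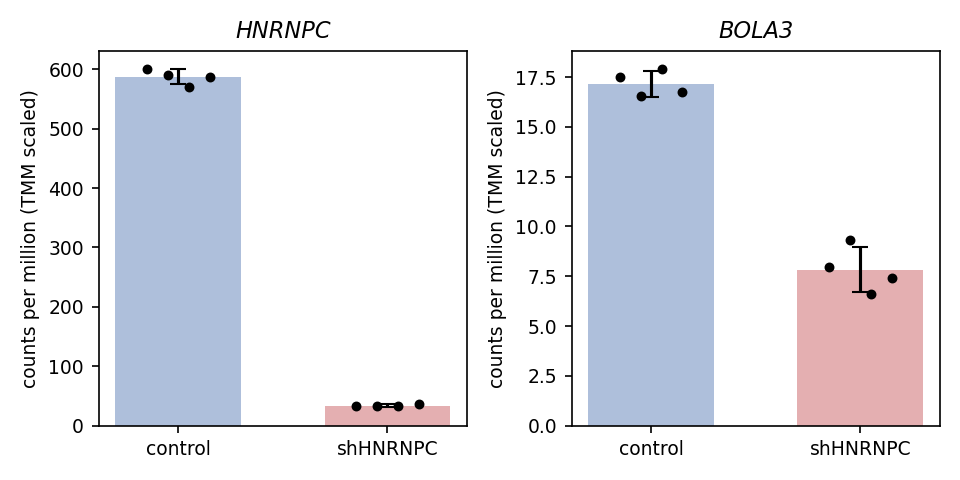
CPM of HNRNPC and BOLA3 in 4 control and 4 shHNRNPC libraries, with points for libraries, bars for means and error bars for the SD. HNRNPC went from a mean of 587 to 33.9 CPM and BOLA3 from 17.2 to 7.82 CPM, with no overlap between the groups.

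**Figure D2:**
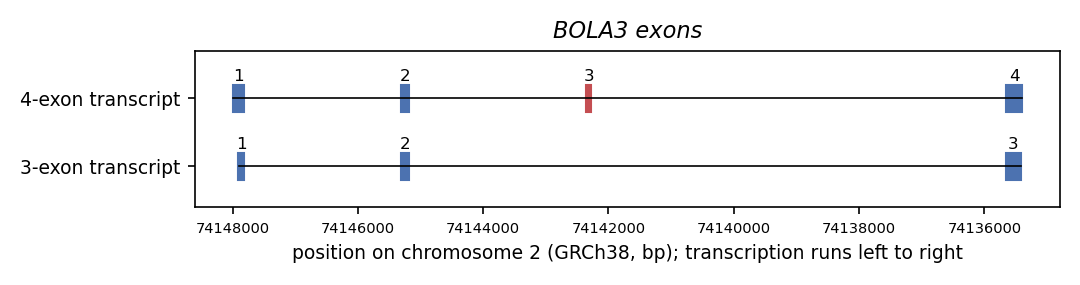
Exons of the 4-exon and 3-exon coding transcripts of BOLA3 on chromosome 2, drawn to scale in GRCh38 coordinates (bp). Exon 3 of the 4-exon transcript (red, 89 bp) is absent from the 3-exon transcript.

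The knockdown was accompanied by small changes in most expressed genes. Of 12001 genes tested, 4640 rose and 4635 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), which is 77.3% of those tested. At least 2-fold changes were found for 380 genes that rose and 630 that fell, whereas 6652 of the calls (71.7%) were below 1.5-fold. The groups did not overlap in CPM for 8492 genes (70.8%), against 2.86% given by chance. The common biological coefficient of variation was 3.02%, so that small differences passed the test. The first principal component of log2 CPM held 80.2% of the variance and separated the groups. The next held 4.51% and set shHNRNPC replicates 1 and 4 (-14.5 and -6.13) apart from replicates 2 and 3 (8.98 and 12.1), with control libraries at -2.10 to 2.25. Residuals within the knockdown group correlated at -0.189 for replicates 1 and 4 and -0.103 for 2 and 3, against -0.489 to -0.371 for the other pairs; the cause of this split was not tested.

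Among protein-coding genes with at least 5 CPM in the higher group and no overlap between groups, those that rose most included ARHGDIB, from 7.99 ± 0.749 to 54.2 ± 1.17 CPM (SD, n = 4; log2 fold change 2.76), and its chromosome 12 neighbour ERP27 (2.73), an endoplasmic reticulum protein. IFIT1 (2.60), FGFR3 (2.55), the neutrophil chemokine CXCL8 (2.45), SPACA6 (2.44) and the creatine kinase CKB (2.38) followed. ALPP (3.27), a placental alkaline phosphatase, and LHX4 (2.79), a LIM homeodomain factor, also rose, but 20.6% and 30.8% of their exon bases overlap other genes. GTPBP6-2 (3.07, SE 0.503) varied between the knockdown libraries (9.31 ± 4.93 CPM) and is uncertain because a near-identical copy can share its reads. Within the same limits the largest falls besides that of HNRNPC were in TMEM156 (-5.07), FOXQ1 (-4.06), a forkhead factor, ZBED2 (-3.31), the phosphodiesterase PDE2A (-3.31) and SIRPB2 (-3.14). AREG, a ligand of the epidermal growth factor receptor, went from 62.6 ± 3.00 to 7.57 ± 1.32 CPM (-3.05). SERPINB2 (-3.03), SPOCK1 (-3.01) and NELL2 (-2.96) were the remaining falls under the naming rule. Of the abundant genes, the chaperone HSP90AA1 rose from 728 to 1855 CPM (1.35, SE 0.0173), and KRT8 (1.10), CENPF (1.00), ANLN (1.34) and the mitochondrial cyclophilin PPIF (1.44) also rose at least 2-fold.

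Of the 34 gene lists fixed before the data were examined, 31 had enough measured members to be tested, and 12 differed from the remaining genes by camera with a preset correlation of 0.01 (9 higher, 3 lower). With an estimated correlation 4 of them held: the mitotic, replication, interferon and cholesterol lists. Counts per list are over all genes tested; adjusted over the list alone they were identical except where stated. The 7-base word GAATGAT lies in annotated 3' UTRs of CENPF, TARDBP, LYRM4, AMT, IL11, RAD51D, CEBPB, DUSP6, INSIG1, SLC7A11, TFRC, BCL2 and METTL14. Of the 1383 tested genes that carry it there, 55.4% fell, against 36.4% of 10373 without it.

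Genes of mitosis rose almost as a whole. Of 49 tested G2/M genes, 48 rose and 1 fell, with a median log2 fold change of 0.79 (camera adjusted p = 1.4e-20; adjusted p = 0.000706 with an estimated correlation). BIRC5, the survivin subunit of the chromosomal passenger complex, went from 47.7 ± 1.94 to 135 ± 2.94 CPM, ANLN, an actin-binding protein of the cleavage furrow, from 402 ± 7.25 to 1019 ± 5.37 CPM (1.34), and DLGAP5, a spindle protein, changed by 1.14. PRC1, which bundles midzone microtubules, rose by 1.22, although 58.4% of its exon bases overlap another gene. Replication genes shifted less, with 29 of 45 G1/S genes higher and 7 lower (median 0.19; camera adjusted p = 0.00187, and adjusted p = 0.0495 with an estimated correlation). The helicase subunit MCM6 (1.12), the phosphatase CDC25A (0.93), E2F2 (0.92) and the ribonucleotide reductase subunit RRM2 (0.84) led this list, RRM2 with 20.2% of exon bases overlapping another gene.

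Interferon-stimulated genes rose as a group. Of 36 tested, 25 rose and 6 fell (26 and 6 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.00082; adjusted p = 0.0495 with an estimated correlation). IFIT1 went from 3.59 ± 0.386 to 21.7 ± 0.489 CPM (SD, n = 4; 2.60), IFIT2 from 8.73 ± 1.14 to 28.4 ± 1.44 CPM (1.70), OASL from 3.84 ± 0.216 to 11.9 ± 0.762 CPM (1.63) and the GTPase GBP1 from 0.736 ± 0.223 to 2.22 ± 0.346 CPM (1.58). Sensors and editors of double-stranded RNA rose in 10 of 12 cases and fell in 1 (median 0.47, camera adjusted p = 0.00658; adjusted p = 0.106 with an estimated correlation). They included DDX58 (0.85), which encodes RIG-I, the helicase DHX9 (0.81) and IFIH1 (0.77), which encodes MDA5. NF-kB and cytokine genes went both ways, with 14 of 24 higher and 6 lower (camera adjusted p = 0.225): CXCL8 (2.45) and IL6 (1.45, 20.7% of exon bases overlapping) rose, while IL1B (-2.51) and IL11 (-1.97) fell.

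A list that pools integrated stress response and unfolded protein response genes fell on balance, with 22 of 35 lower and 12 higher. Its median was -0.52 (camera adjusted p = 0.00605, and camera adjusted p = 0.147 with an estimated correlation). The 2 responses were not tested apart, so a fall of the unfolded protein response by itself was not shown. The chaperone CALR, a member chosen after its values were seen, rose (1.18). CHAC1, which degrades glutathione, was at 3.35 ± 0.307 CPM after knockdown, 20.8% of control (-2.26), CEBPB from 101 ± 5.46 to 24.2 ± 0.503 CPM (-2.07) and SESN2 from 78.0 ± 1.76 to 21.9 ± 0.942 CPM (-1.83). The asparagine synthetase gene ASNS, with 44.6% of exon bases overlapping another gene, fell from 431 ± 12.2 to 103 ± 1.14 CPM (-2.06). Without its 8 carriers of GAATGAT the median of this list was -0.28 (camera adjusted p = 0.0465). Immediate early and AP-1 genes fell in 19 of 27 cases and rose in 5 (median -0.46; camera adjusted p = 0.00082; adjusted p = 0.147 with an estimated correlation). ETV5 (-2.05), SPRY4 (-1.88) and DUSP6 (-2.04, 40.5% of exon bases overlapping), which are induced by or restrain ERK signalling, fell, while FOS rose (1.30).

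Cholesterol synthesis and uptake genes rose in 20 of 22 cases and fell in 1 (median 0.57; camera adjusted p = 1.5e-05; adjusted p = 0.0495 with an estimated correlation). TM7SF2, a sterol reductase (1.53), and INSIG1 (1.45) and LSS (0.94), which encode a sterol sensor partner and an enzyme of the pathway, also rose.

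Cytosolic ribosomal protein genes fell together by a modest amount, in 71 of 76 cases with 3 higher (median -0.33; camera adjusted p = 1.6e-18; adjusted p = 0.181 with an estimated correlation). RPL3 went from 2992 ± 63.0 to 1753 ± 31.6 CPM (-0.77) and RPS18 from 1748 ± 74.3 to 1108 ± 38.7 CPM (-0.66), while RPS26 rose (0.60). RPS10 rose (1.54) from 0.621 ± 0.259 to 1.82 ± 0.132 CPM, a value left uncertain by shared exons (39.4% of bases) and a near-identical copy. The list held 7.73 ± 0.0911% of counts in the control libraries and 5.97 ± 0.0724% in the knockdown libraries (exact permutation test, two-sided, p = 0.0286, n = 4 per group). The 10 most abundant genes of each library took 5.19 ± 0.0578% and 4.58 ± 0.0636% of counts (exact permutation test, two-sided, p = 0.0286). Nuclear genes of the respiratory chain rose slightly. In complex I, 23 of 37 rose and 6 fell (median 0.20; camera adjusted p = 0.0138; adjusted p = 0.260 with an estimated correlation), led by NDUFA1 (0.70, 44.5% of exon bases overlapping), NDUFB1 (0.58), NDUFB3 (0.57) and NDUFA12 (0.57). In complexes II to V, 25 of 38 rose and 7 fell (median 0.14; camera adjusted p = 0.00569; adjusted p = 0.311 with an estimated correlation). UQCR10 (0.84), ATP5MC1 (0.67) and ATP5MF (0.60) rose and UQCRB fell (-0.81). Genes of the mitochondrial genome were not among those analysed here.

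**Figure D3:**
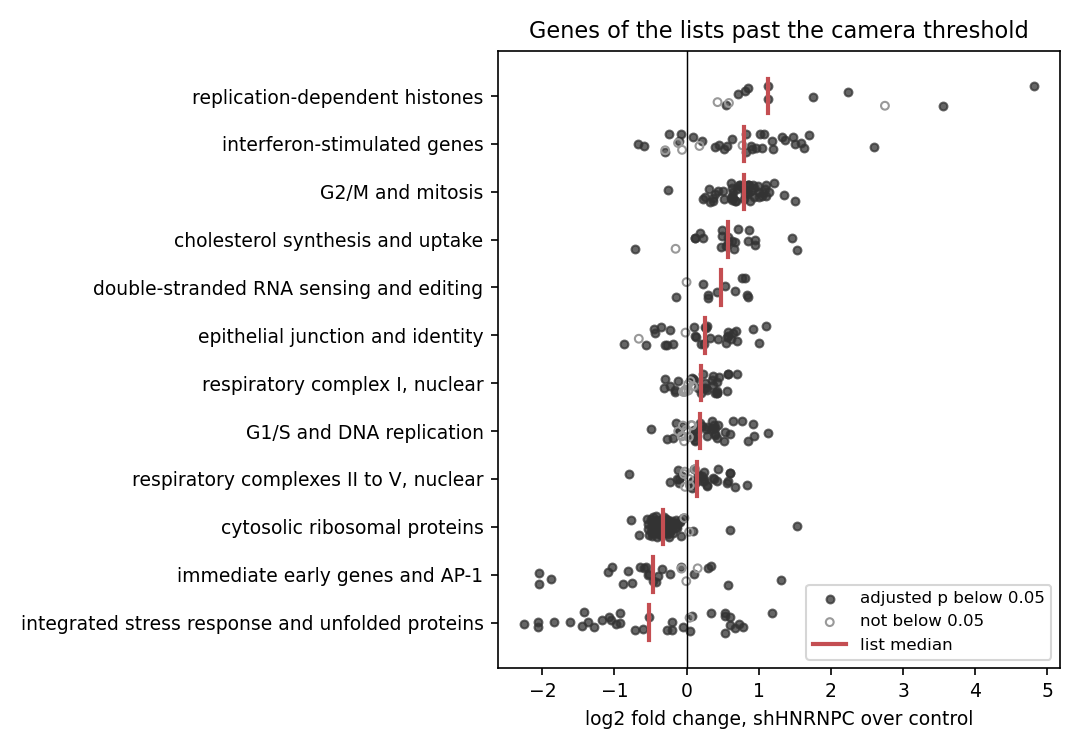
Log2 fold change (shHNRNPC over control) of each tested gene in the 12 lists that passed camera with the preset correlation, with filled points for genes past an edgeR adjusted p of 0.05 and red bars for list medians. The G2/M list lies almost entirely above 0 (48 of 49 rose) and the ribosomal protein list almost entirely below it (71 of 76 fell).

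Iron-sulfur cluster assembly genes, to which BOLA3 belongs, went both ways, with 13 of 28 higher and 8 lower (camera adjusted p = 0.773). LYRM4, a partner of the cysteine desulfurase, went from 17.5 ± 1.48 to 8.31 ± 1.22 CPM (SD, n = 4; -1.07), and the desulfurase NFS1 fell (-0.67). Lipoate enzymes and substrates rose in 10 of 16 cases and fell in 4 (median 0.20; camera adjusted p = 0.223). LIAS, the iron-sulfur enzyme that makes lipoate, fell (-0.63), as did GLDC (-0.96, from 1.07 ± 0.225 to 0.544 ± 0.111 CPM) and AMT (-1.02) of the glycine cleavage system, and LIPT2 rose (0.73). Exon overlap with other genes is 63.1% for AMT and 31.0% for LIPT2.

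Splicing factors were not shifted against other genes by camera. The hnRNP family rose in 16 of 28 cases and fell in 8 (median 0.10, mean -0.01, camera adjusted p = 0.188). This list includes HNRNPC, the knocked-down gene, which is among the 8 falls and lowers the mean, and camera was not run without it. Besides HNRNPC, HNRNPUL2 (0.79, 44.2% of exon bases overlapping), HNRNPAB (0.74) and TARDBP (0.61, 29% overlapping) changed most. SR proteins and core factors rose in 25 of 41 cases and fell in 13 (camera adjusted p = 0.124), with SRSF8 (-0.91), CLK4 (0.72) and TRA2A (0.56) among the larger changes. U2AF1 is uncertain: its reads can be shared with a near-identical copy, and its change (0.71, edgeR adjusted p = 0.0443) was lost when control replicate 1, 2, 3 or 4 or shHNRNPC replicate 3 was left out (edgeR adjusted p = 0.0568, 0.104, 0.105, 0.0624 and 0.0930; range over all alternatives 0.00013 to 0.105). Nonsense-mediated decay factors (7 of 16 higher, 4 lower, camera adjusted p = 0.739) moved little, with UPF3B (0.38), UPF2 (0.29) and MAGOH (-0.28). Polyadenylation factors (8 of 20 higher, 9 lower, median -0.02, mean 0.00, camera adjusted p = 0.826) included PABPC1 (-0.57), which encodes the cytoplasmic poly(A)-binding protein, PAPOLA (0.40), PABPN1 (0.37) and WDR33 (0.35, 25.6% overlapping). Of the m6A machinery, 7 of 18 rose and 4 fell (camera adjusted p = 0.487); the reader YTHDF2 (0.91) and RBM15B (0.75) rose, and the methyltransferase subunits METTL14 (-0.47) and METTL3 (-0.33) fell.

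Epithelial junction and identity genes rose in 21 of 32 cases and fell in 9 (median 0.25; camera adjusted p = 0.0415; adjusted p = 0.331 with an estimated correlation). KRT8 (1.10), the transcription factor GRHL1 (1.01) and the protease ST14 (0.92) rose and KRT7 fell (-0.86). This call was lost without shHNRNPC replicate 4 (median 0.23, camera adjusted p = 0.0523) and without replicates 1 and 4 (median 0.24, camera adjusted p = 0.0532). Squamous basal genes went both ways (12 of 24 higher, 10 lower, median 0.10, camera adjusted p = 0.739), with FGFR3 (2.55) and KRT17 (1.70) higher and KRT6A (-1.62) and KRT15 (-1.05) lower. Their median was -0.04 with DESeq2 and -0.05 with no filter. Squamous differentiation genes (8 of 20 higher, 10 lower, median -0.22, camera adjusted p = 0.365; median -0.61 with DESeq2 and with no filter, -0.55 with the 1 CPM filter) included falls of SERPINB2 (-3.03), KLK6 (-2.23, 20.3% of exon bases overlapping), LCN2 (-1.37) and SCEL (-1.34), and their median was 0.10 without the carrier of GAATGAT in this list. Mesenchymal and matrix genes rose in 19 of 42 cases and fell in 19; their median was 0.10, their mean -0.18 and camera gave the lower direction (adjusted p = 0.739). With DESeq2 and with no filter the median was -0.17 and -0.16. Tenascin C, TNC, went from 476 ± 6.23 to 125 ± 2.05 CPM (-1.93), and SERPINE2 (-2.33) and ZEB1 (-1.66) fell as well.

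The remaining pathway lists were not shifted by camera, while single members moved strongly. Among p53 targets 9 of 30 rose and 13 fell (camera adjusted p = 0.259), with lower GDF15 (-2.63), SESN2 (-1.83), PLK3 (-1.21) and BBC3 (-1.20). Hypoxia and glycolysis genes rose in 21 of 32 cases and fell in 9 (camera adjusted p = 0.0918); NDRG1 went from 171 ± 3.51 to 39.1 ± 1.08 CPM (SD, n = 4; -2.13) and VEGFA fell (-1.64), while ADM (1.63) and PFKP (1.11) rose. Of NRF2 and ferroptosis genes 18 of 30 rose and 6 fell (camera adjusted p = 0.0918), with a fall of the cystine transporter SLC7A11 (-1.37) and rises of HMOX1 (1.31), the transferrin receptor TFRC (0.94) and SRXN1 (0.89, 85.0% of exon bases overlapping). Apoptosis regulators rose in 14 of 31 cases and fell in 10 (camera adjusted p = 0.874), including BCL2 (-1.11), CFLAR (-0.97) and BCL2L11 (1.00). Homologous recombination and Fanconi genes rose in 16 of 33 cases and fell in 12 (camera adjusted p = 0.944), with RAD51D (-1.09), RBBP8 (-0.67), FANCF (-0.56) and RAD54L (0.63, 25.1% overlapping).

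Few markers of other cell types were measured, at levels from below 1 CPM to 216 ± 5.95 CPM (SD, n = 4) for CD68 in the control samples. Of fibroblast markers 2 of 3 rose (camera adjusted p = 0.348): COL1A1 went from 3.25 ± 0.0917 to 7.86 ± 0.222 CPM and LUM from 0.197 ± 0.0521 to 0.597 ± 0.146 CPM, and PDGFRB was at 0.261 and 0.410 CPM (edgeR adjusted p = 0.146, and 0.0436 without shHNRNPC replicate 1, up to 0.389 under the alternatives). Leukocyte markers gave 0 of 2 higher and 1 lower (camera adjusted p = 0.225), CD68 (-1.06, to 104 ± 1.53 CPM, with 85.8% of exon bases overlapping) and CSF1R (-0.11, edgeR adjusted p = 0.586). Endothelial markers gave 1 of 4 higher and 2 lower; their median was -0.22 (-0.39 with DESeq2 and with no filter, -0.64 with the 1 CPM filter) and camera gave the higher direction (adjusted p = 0.907). Without control replicate 3, control replicate 4 or shHNRNPC replicate 4 this median was -0.36, -0.10 and -0.39. EGFL7 rose (0.99) and VWF fell (-1.15). ESAM (-0.64, edgeR adjusted p = 0.0183) was lost without control replicate 1 or 4 or shHNRNPC replicate 1 or 3 (edgeR adjusted p = 0.0525, 0.0683, 0.0605 and 0.0658, and 0.00325 at the lowest of the alternatives). Glandular and liver markers and nuclear long noncoding RNAs had 0 genes to test.

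Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails and so report on RNA selection, rose in 10 of 13 cases with 0 lower (11 and 0 adjusted over the list alone; median 1.12; camera adjusted p = 0.0367; adjusted p = 0.604 with an estimated correlation). The median was 1.78 with DESeq2 and 1.76 with no filter. The knockdown libraries differed in these genes. The counts of H1-4 were 357, 19, 8 and 238 in shHNRNPC replicates 1 to 4, and those of H3C2 were 189, 10, 12 and 134, against 2 to 16 and 3 to 13 in the control libraries. The summed histone CPM was 307, 233, 237 and 271 in the knockdown libraries and 155 to 165 in the control libraries. Mean log2 CPM of the G1/S list was 6.15 to 6.17 in the control libraries and 6.396 to 6.4002 in the knockdown libraries. The list call was lost without control replicate 3 or 4 or shHNRNPC replicate 1 or 4 (camera adjusted p = 0.0543, 0.0527, 0.0502 and 0.0523; median 1.12, 1.17, 0.99 and 1.07), and without both of the latter its median was 0.54 with 6 higher and 0 lower (camera adjusted p = 0.145); without the 2 members that carry GAATGAT the median stayed at 1.13, but the smaller list missed the threshold (camera adjusted p = 0.0661). H1-4 (4.82, edgeR adjusted p = 0.0343) and H3C2 (3.55, edgeR adjusted p = 0.0449) were each lost without control replicate 1, 2, 3 or 4 or shHNRNPC replicate 1 or 4 (edgeR adjusted p from 0.0623 to 0.0845 and from 0.0864 to 0.105), at log2 fold changes of 3.94 to 5.93 and 2.76 to 3.86. H3C8 (2.24) and H4C8 (1.76) also rose.

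**Figure D4:**
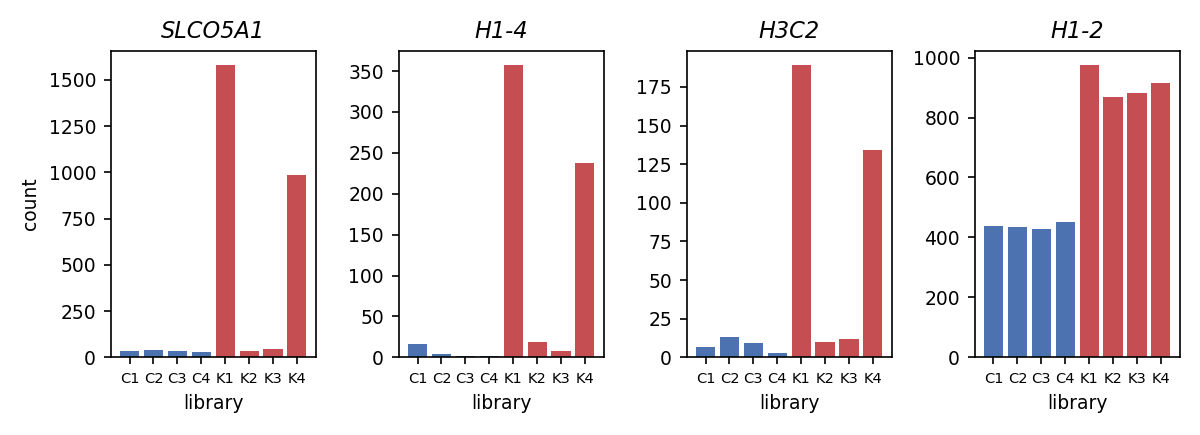
Raw counts in control libraries C1 to C4 and shHNRNPC libraries K1 to K4 for SLCO5A1, H1-4, H3C2 and H1-2. Replicates 1 and 4 of shHNRNPC hold 1578 and 985 counts of SLCO5A1, a gene chosen after its values were seen, against 32 and 45 in replicates 2 and 3, whereas H1-2 is at 867 to 974 in all knockdown libraries.

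Zinc finger genes, whose transcripts are rich in Alu elements that HNRNPC is known to keep from being spliced in, were not shifted against other genes by camera. Of 335 tested, 106 rose and 121 fell (106 and 118 adjusted over the list alone), with a median of -0.02 (camera adjusted p = 0.813 and, with an estimated correlation, adjusted p = 0.772, each over this class alone; camera gave the lower and fry the higher direction). ZNF695 (1.21) and ZNF680 (1.10) rose, and ZNF497 (-2.20, 45.3% of exon bases overlapping) and ZNF426 (-1.15) fell. Only 5 long noncoding RNA genes were tested, of which 1 rose (20%, 95% exact Clopper-Pearson interval 0.505 to 71.6%) and 2 fell (40%, 5.27 to 85.3%), against 38.7% and 38.6% of protein-coding genes (Fisher's exact test, two-sided, p = 0.655 and p = 1.00). Among noncoding genes with at least 5 CPM in the higher group and no overlap between groups, the largest changes were in SLC35E2A (-0.53, 28.8% of exon bases overlapping), TSTD3 (-0.48, 23.0% overlapping) and LOC389831 (-0.45).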

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

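The criterion for an outlying library was fixed before the data were examined, and the count of outliers per library was made only after the values were seen. In 294 groups of 4 values (the named genes and 4 library measures, each in both groups), the highest or lowest library stood apart from the others in 20 (6.80%), and chance gives about 1 in 20. Of these, 7 were in shHNRNPC replicate 1, 4 in control replicate 3, 3 each in control replicate 1 and shHNRNPC replicate 2, and 1 each in control replicate 4 and shHNRNPC replicates 3 and 4.

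In shHNRNPC replicate 1 the CPM of UQCRB (42.1, others 43.5 to 43.7), DDX58 (9.66, others 11.74 to 12.03), ST14 (347, others 356 to 358) and RBM15B (86.2, others 90.2 to 90.6) was low, and that of ZEB1 (1.42, others 0.694 to 0.804), ZNF695 (27.9, others 25.9 to 26.02) and ZNF680 (67.9, others 64.8 to 65.1) was high. In shHNRNPC replicate 2 the CPM of TRA2A (70.7, others 78.8 to 80.1), NDUFA12 (108, others 113.5 to 114.2) and BCL2 (4.17, others 4.76 to 4.86) was low. IL11 was high in shHNRNPC replicate 3 (6.58 CPM, others 4.66 to 4.96) and BCL2L11 low in shHNRNPC replicate 4 (28.9 CPM, others 30.9 to 31.1).

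Among control libraries, RPS10 (1.01 CPM, others 0.445 to 0.533), PABPN1 (8.01 CPM, others 6.32 to 6.58) and H1-4 (0.473 CPM, others 0.0625 to 0.118) were high in replicate 1. In replicate 3, ARHGDIB (6.87 CPM, others 8.35 to 8.39), NELL2 (7.46 CPM, others 8.95 to 9.24) and the ribosomal protein share of counts (7.59%, others 7.77 to 7.79%) were low and H4C8 (0.781 CPM, others 0.349 to 0.384) was high. UPF3B was low in replicate 4 (30.9 CPM, others 33.27 to 33.31).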

How the results depend on the processing

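The fits without shHNRNPC replicates 1 and 4 and without genes carrying GAATGAT in the 3' UTR were chosen only after the data were seen. Of 2281 values of 143 named genes under the alternatives, 2256 kept their direction and side of the threshold, 23 fell below it, 1 rose past it and 1 changed sign; of 496 list values these numbers were 445, 14, 35 and 2. The calls by direction stayed within 1.5 times the main counts in every fit: 4601 higher and 4632 lower with DESeq2, 4354 and 4916 with upper quartile factors, 4400 and 4862 with library size alone, 4698 and 4895 with no filter, and 4931 and 4355 after removal of the length and GC trend. Of the DESeq2 calls 9004 were shared with edgeR, all in the same direction. Without shHNRNPC replicates 1 and 4 there were 4439 higher and 4386 lower genes and 10 lists, and without the GAATGAT carriers 4084 and 4026 of 10618 genes and 11 lists. The number of lists past the threshold was 12 with the preset correlation, 4 with an estimated correlation, and 29 and 31 with fry, directional and mixed, which ask another question; the cause was not tested further. In limma's fry the zinc finger class turned to the higher direction (directional, adjusted p = 0.142) and passed the mixed test (adjusted p = 9.9e-11), each over this class alone. The homologous recombination list turned to the lower direction with directional fry (adjusted p = 0.00625), and the endothelial list turned with no filter (camera adjusted p = 0.855), where more genes are tested. The share of long noncoding RNA genes that rose was 20% also at 2-fold, then above that of protein-coding genes, which rests on 1 gene. Mean correlations of libraries within and between groups were 0.994 and 0.964 with a prior count of 0.5, and 0.996 and 0.960 with the 1 CPM filter; the cause was not tested. The log2 fold change of CSF1R ranged from -0.24 to 0.05 when single libraries were left out and changed sign without control replicate 1 (0.0488); the cause was not tested. The histone list was also lost with the 1 CPM filter (median 0.76, camera adjusted p = 0.0626), and H3C2 with no filter (edgeR adjusted p = 0.0606).

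With the replicate number as a block, 4605 genes rose and 4614 fell, 12 lists passed, and HNRNPC and BOLA3 changed by -4.11 and -1.14; of the named genes only H3C2 lost its call (edgeR adjusted p = 0.0973). Same-numbered libraries did not deviate together (correlations of residuals 0.016, -0.064, -0.038 and -0.0039), and not every library correlated best with its own number, so the numbers were not read as pairs. Leaving out mitochondrial-genome genes was not run, because the table held 0 of them.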

Other observations

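The comparison with a control hairpin sequence, the choice of the terms described next, the values of SLCO5A1 and the share of changed genes without GAATGAT came only after the results were seen; the tests of where GAATGAT lies and of its copies were planned after the word was found, and that of runs of adjacent genes after the adjacent pairs were counted, but each before its own result. Of 2221 gene ontology and pathway terms with 15 to 300 tested genes, 111 passed camera with the preset correlation (88 higher, 23 lower) and 0 with an estimated correlation, with which 192 had an unadjusted p under 0.05. The term for presentation of exogenous peptides on MHC class I also holds proteasome subunits such as PSMB6 and PSMD1, which were not tested apart. Its genes rose in 49 of 64 cases and fell in 8 (median 0.30, camera adjusted p = 2.7e-05, and camera adjusted p = 0.551 with an estimated correlation). They included the chaperone CALR, from 245 to 557 CPM (log2 fold change 1.18), TAPBP (1.14), which loads peptides, and the immunoproteasome subunit PSMB8 (1.19, 20.6% of exon bases overlapping another gene). Genes of the response to heat rose in 47 of 72 cases and fell in 12 (median 0.16, camera adjusted p = 0.000767, and camera adjusted p = 0.374 with an estimated correlation). HSP90AA1 (1.35) and HSPA1A (1.17) rose, but HSPA1A can share reads with its near-identical copy HSPA1B (0.98, 36.5% of exon bases overlapping). HSPA1L, whose 3' UTR carries GAATGAT, fell from a low level (-1.12, from 1.13 to 0.514 CPM).

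Aminoacyl-tRNA synthesis genes fell in 30 of 44 cases and rose in 6 (median -0.23; camera adjusted p = 0.000859; adjusted p = 0.537 with an estimated correlation). WARS1 (-1.07), CARS1 (-0.93), SARS1 (-0.90) and MARS1 (-0.88), which charge tRNAs with tryptophan, cysteine, serine and methionine, all fell. Kinetochore genes, with a rise of SPAG5 (1.14) and a fall of DYNC1I1 (-1.30), rose in 54 of 82 cases and fell in 14 (camera adjusted p = 0.00119; adjusted p = 0.374 with an estimated correlation). Oocyte maturation genes, with a rise of AURKA (1.09) and a fall of PRKACB (-2.54), rose in 46 of 71 cases and fell in 11, and phagosome genes, with a rise of the scavenger receptor OLR1 from 0.257 to 4.35 CPM and falls of RAB7B (-2.85) and TUBAL3 (-2.29), rose in 63 of 93 cases and fell in 20 (camera adjusted p = 0.000859 for both; adjusted p = 0.374 and 0.506 with an estimated correlation). The counts of SLCO5A1, a transporter gene chosen after its values were seen, were 1578, 32, 45 and 985 in shHNRNPC replicates 1 to 4 and 30 to 39 in the control libraries.

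The first pattern is the number of genes changed. Of the 35 splits of the 8 samples into 4 and 4, only the real one, 1 split, reached its 9275 genes past edgeR's threshold. The highest other split gave 0 (at most 363 at an unadjusted p under 0.05). A share of 1 in 35 is the smallest that these splits allow. Every other split mixes the groups, which widens the spread on each side and by itself lowers the count. Chance is thus made less likely to that extent but is not excluded. The chromosome median farthest from that of all genes was only 0.106 away, on chromosome 22, which argues against a copy number difference of whole chromosomes, but one of a segment stays open for the genes in it: the run of 20 adjacent genes farthest from that median lay 0.868 above it, on chromosome 6, against 0.77 at the highest of 1000 shuffled orders (this run holds a cluster of histone genes, and position was not separated from gene class), and adjacent genes that both fell at least 2-fold numbered 51, against 49 at the highest. Off-target action of the hairpin stays open for the 1383 carriers of GAATGAT, the word with the most negative score among 15839 in 3' UTRs, which occurs in HNRNPC, as do 5011 of these words, since they differed from other genes by -0.18 (SE 0.0175) on the log2 scale, but its sites do not account for the number: of the 10373 genes whose 3' UTR lacks it, 77.2% passed the threshold (4237 rose, 3774 fell), against 81.3% of carriers. A direct effect of HNRNPC loss is the explanation named by the design, and with 1 hairpin group and no rescue it was not separated from the hairpin's other effects, through other sites or downstream of its targets.

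The next pattern is the carriers of GAATGAT. The word had a z of -10.4, against -5.44 for the next most negative word, GATGGTT, which does not occur in HNRNPC, and 5.63 for the most positive word, and it lies before the stop codon of HNRNPC, in the contexts GGAGAGGATGGCAGAATGATT and CAGTAGAGATGAAGAATGATA. Words were looked for in HNRNPC transcripts in their own direction only, so the reverse complement of HNRNPC was not searched. Genes with GAATGAT only in the 3' UTR lay -0.139 (SE 0.0257) from genes with it only before the stop codon. The seed site of a small RNA would predict this direction. The word was picked for its low 3' UTR carriers, however, which favours this direction. The contrast was also negative for GATGGTT (-0.083, SE 0.027) and ATGGTTA (-0.062, SE 0.031), which do not occur in HNRNPC, and for AATGATA (-0.053, SE 0.026), which does. These words were themselves picked as the most negative after GAATGAT, which favours the same direction. AATGATA also shares most of its bases with GAATGAT, and ATGGTTA with GATGGTT. They are thus not independent controls, and the direction of the contrast does not decide for or against a seed site. Whether more copies go with a larger fall was not settled, since genes with at least 2 copies differed from genes with 1 copy by -0.0685 (SE 0.046). A candidate explanation is a seed of the knockdown hairpin that matches this word, which could not be compared with its sequence because neither hairpin's sequence is given in the sources used here.

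The words highest among genes that rose, GGAGAAC (z = 5.63) and GTGTCAC (z = 5.18), were 2 of 2 found in either strand of GTTCTCCGAACGTGTCACGT, a control hairpin sequence in wide use. A hypothesis is that the control cells may have carried such a hairpin, whose seed sites then lie lower in the control samples; the labels give treatment None for all 8 samples, the knockdown included, and do not say what the control cells carried, and the sequence was compared only after these words were seen. GTGTCAC lies in that sequence as written and GGAGAAC in its reverse complement, so a single strand does not carry both. The 24 tested words from either strand had a median z of 0.575, from 5.63 for GGAGAAC to -2.48 for CGTGACA. Genes with GGAGAAC or GTGTCAC only in the 3' UTR lay 0.0432 (SE 0.0196) above genes with either only before the stop codon. This leaves open whether these words act from the 3' UTR.

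The last pattern weighed is the fall of ribosomal protein genes. After removal of the length and GC trend their median log2 fold change was -0.32, and the highest median under the other scalings was -0.325. The 26 members whose exons overlap no other gene in position had a median of -0.346. This argues against the length and GC trend, the scaling and overlapping genes as the cause. Reads shared with pseudogenes or copies elsewhere in the genome were not measured, so that explanation stays open. As a hypothesis, messenger RNAs that begin with a terminal oligopyrimidine tract (TOP) may fall as a class: of 20 TOP genes outside the list 17 fell and 1 rose, with a median of -0.297. This was tested on the same samples and stays a hypothesis.

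Other hypotheses did not show the predicted result, within what each test could measure. Adjacent genes that both rose at least 2-fold numbered 16, within the 18 that bounds 95% of shuffled orders, while those that both fell numbered 51, beyond every shuffle, which had not been predicted. Genes with an annotated antisense Alu core differed from genes with a sense core by 0.0026 (95% bootstrap interval -0.0278 to 0.0397), so no lower level of the former was seen. Only annotated spliced transcripts were searched for these cores. Alu elements in introns and Alu exons outside the annotation were not covered, so the test cannot decide whether such exons were spliced in. Across genes, which are not independent replicates, intron length and fold change had a median Spearman's rho of -0.0059 over 16 bins of expression and transcript length.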
